A study of Mus musculus with 4 samples.

How the data were processed

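RNA was sequenced from whole testes of 4 mice at postnatal day 25, with 1 library per mouse. Of these, 2 mice were labelled wild type (WT) and 2 were labelled deficient in Ptbp2 through a conditional knockout (cKO), all of the C57BL/6 strain. Ptbp2 encodes a polypyrimidine tract binding protein, an RNA-binding protein that regulates alternative splicing. Per the labels' protocols, the paired-end libraries were made with a ScriptSeq kit, and the protocols name both poly(A) selection and depletion of ribosomal RNA. The submitters' processing notes name the mouse genome builds mm9 and mm10 without saying which step used which. The aligner, the program that counted reads, the splicing caller and the filters before deposit are not given in the sources used here.

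For expression, the authors deposited RPKM (reads scaled to gene length and library size) for each library and the mean of each genotype, per the file headers. The table holds 988 genes. The authors' deposited log2 fold change equals the log2 ratio of the mean RPKM of cKO over WT within 0.0322. The deposited adjusted p-value has 4 decimals and is printed as 0 for 573 genes. The test and the adjustment behind it are not given in the sources used here. The smallest absolute log2 fold change in the table is 0.6 and the largest adjusted p-value is 0.0099. The table thus fits a cutoff of 0.01 on the adjusted p-value, and whether a fold filter was also used cannot be told. Genes outside it were not analysed here, so the table gives no background of unchanged genes. RPKM is a share of a library's reads: where abundant transcripts fall, the RPKM of other transcripts rises. RPKM values have 2 decimals, the lowest is 0.2, and neither read totals nor gene lengths accompany them. Steps of single reads were not resolved, the depth of each library is therefore unknown, and no counting interval is given.

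For splicing, the authors deposited 1 value per event, ΔPSI, the change in percent spliced in between the genotypes in percentage points, per the file headers. The headers do not state which genotype was subtracted, so changes are given here as positive or negative ΔPSI and not as more or less inclusion. No value per library, coverage or p-value accompanies an event, so no replicate error can be given for ΔPSI. The table holds 1223 events, of which 308 rows carry no gene name. These rows were given the name printed above them, and all 305 of those with an annotated gene lie on that gene's chromosome and strand. The event codes were read as cassette exon (cass), retained intron (iret), tandem cassette exons (taca), alternative 3' and 5' splice sites (alt3, alt5) and mutually exclusive exons (mutx). A second deposited table holds 257 of the events. Each was found in the larger table by gene, type and ΔPSI within 0.5 points, and they are all events with an absolute ΔPSI of at least 20 points.

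The splicing coordinates were taken as mm9, counted from 0 at the start. Of 736 cassette exons in annotated genes, 706 have the length of an annotated exon when the end minus the start is taken, against 79 with 1 added, and 18 have the coordinates of an exon in the mm10 annotation (GENCODE release M21). Coordinates are printed counted from 1 and were not converted. Whether an exon is coding was judged by its length among the exons of that gene in GENCODE M21, not by its position. Gene names were matched through symbols and synonyms of the RefSeq table of that later build for 977 of the 988 expression genes and 912 of the 915 spliced genes.

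The expression values were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with Benjamini-Hochberg (BH) adjustment over the genes tested, a threshold of 0.05 and no block. A fold change on this scale understates the change of genes with low RPKM. Because the genes had been selected by the authors on the same libraries, this test shows how large each difference is against the spread between mice and is not independent evidence of it. Values were also simulated with the spread of these libraries, for cKO against WT over 988 genes with 200 changed. There limma recovered 13% of the genes changed by 1 on the log2 scale and 56% of those changed by 2. Of its calls there, 4.17% were unchanged genes. The deposited genes were instead selected for difference, with 879 of 988 at an unadjusted p under 0.05. The simulated rates therefore do not describe the test as run on them. With 2 mice against 2, the smallest two-sided exact permutation p is 0.333. Shares were compared with two-sided Fisher's exact tests and medians with two-sided permutation tests of 100000 resamples, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Events with a ΔPSI of 0 were left out of tests of direction. On simulated data without a difference, the Fisher test called 4% of sets and the median test 5.5%. Figures were drawn with matplotlib 3.10.9.

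The groups, tests, alternatives and gene lists were fixed before the data were examined. The cell type lists hold markers of spermatogonia (16 genes), spermatocytes (20), spermatids (33), Sertoli cells (21), Leydig cells (10), peritubular myoid cells (6), macrophages (13), endothelium (5), erythroid cells (6) and epididymis (7). The functional lists hold genes of the actin cytoskeleton (95), adhesion and junctions (61), membrane traffic (61), RNA binding (65) and known targets of PTB proteins (40). The genes named are Ptbp1, Ptbp2 and Ptbp3, the 10 largest changes in each direction in the expression table without predicted models, members of the lists, the 10 largest positive and negative ΔPSI with 1 event per gene, and the 10 genes in both tables with the largest absolute ΔPSI. A gene named outside this rule is said to be. Alternatives changed the pseudocount to 0.1, the thresholds, the expression filter, the handling of predicted gene models and of several events in 1 gene, the matching of names, and the libraries used. The planned count models, low-count filters, splicing p-value thresholds, splicing coverage filter and fits of splicing per library were not run, since the tables used hold no read counts, no p-value or coverage for an event and no splicing value per library.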

Results

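The data compared testes of WT mice with testes of mice labelled deficient in Ptbp2 at postnatal day 25, an age by which the first wave of spermatogenesis has produced round spermatids. The title of the series places the question in splicing control and cell communication during spermatogenesis. Expression was given as RPKM for 988 genes in 4 libraries, 2 per genotype, each from 1 mouse. Splicing was given as 1 ΔPSI for each of 1223 events in 915 genes. Over the 925 genes listed as lower in the libraries labelled cKO, the median RPKM was 23.5 and 26.1 in WT libraries 1 and 2, against 6.71 and 2.59 in labelled cKO libraries 1 and 2. Over the 63 genes listed as higher, it was 11.5 and 11.6 against 16.1 and 21.1.

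Ptbp2 itself was measured at 65.7 and 66.6 RPKM in WT libraries 1 and 2, and at 111 and 98.2 RPKM in labelled cKO libraries 1 and 2. The targeted gene was thus higher in the libraries labelled cKO, against a simple reading of the label. RPKM over a whole gene does not separate a deleted part from the rest, so it does not check the labels, and "the libraries labelled cKO" is kept throughout. The authors' deposited table gives Ptbp2 a log2 fold change of 0.66 with an adjusted p of 0.0044. In limma on log2(RPKM + 1) its difference was 0.65 ± 0.27 (SE), with a BH-adjusted p of 0.0684, which ranged from 0.00192 to 0.476 over the alternative settings. Ptbp1 and Ptbp3, the related genes, are not in the expression table. The splicing table lists 1 Ptbp2 event, a cassette exon of 34 nt on chromosome 3 (mm9 119427530 to 119427563) with a ΔPSI of -9, whose length is that of a coding exon of the gene.

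Genes expressed in spermatids were far lower in the libraries labelled cKO. Prm1 and Prm2, which encode the protamines that package sperm DNA, fell from 332 ± 112 and 210 ± 56.4 RPKM (SD, n = 2) in WT to 11.6 ± 10.6 and 6.67 ± 6.93 RPKM in the libraries labelled cKO. Their log2 fold changes in the authors' deposited table were -4.84 and -4.98. Tnp1 and Tnp2, the transition protein genes that act before the protamines, had log2 fold changes of -4.80 and -4.71 in the authors' deposited table, and the spermatid maturation gene Spem1 one of -4.67. The acrosomal gene Acrv1 fell from 15.7 ± 0.785 to 2.66 ± 2.29 RPKM (SD, n = 2), and the sperm tail gene Akap4 had a log2 fold change of -3.56 in the authors' deposited table. Of the 33 genes in the spermatid list, 26 are in the table and all 26 were lower, with log2 fold changes in the authors' deposited table from -2.37 for Spaca1 to -4.98 for Prm2 and a median fold of 9.38. The list also includes Catsper1 of the sperm calcium channel (-3.34), the sperm glycolysis gene Gapdhs (-2.82) and the kinase genes Tssk1 (-2.51) and Tssk2 (-3.42). The values of these kinase genes may be uncertain if related copies share reads, which was not checked. The same holds for Iqcf1 (-4.44) and H2afb1 (-4.33), members of gene families among the 10 largest falls, which further include Rpl34 (-4.58), Slfnl1 (-4.40) and Prss37 (-4.34).

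In all, 925 of the 988 genes (93.6%) were listed as lower in the libraries labelled cKO, 458 of them by 4-fold or more, and 63 as higher, 22 of them by 2-fold or more. All 988 genes separate the genotypes without overlap, which chance gives 33.3% of the time for 1 gene, but the table was selected for difference. In limma with BH adjustment at 0.05, 829 genes fell and 19 rose, with 858 and 21 at an unadjusted p under 0.05. All 26 spermatid genes fell, also when adjusted over the list alone. For Prm1 the limma difference was -4.99 ± 0.74 (SE), with an adjusted p of 0.0177. Without WT library 1 or WT library 2, limma gave 388 and 353 lower genes and 0 higher genes in each case (0 and 1 at an unadjusted p under 0.05), and without labelled cKO library 1 or 2 it gave 925 lower and 63 higher genes. In each of these 4 fits all 26 spermatid genes fell.

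**Figure D1:**
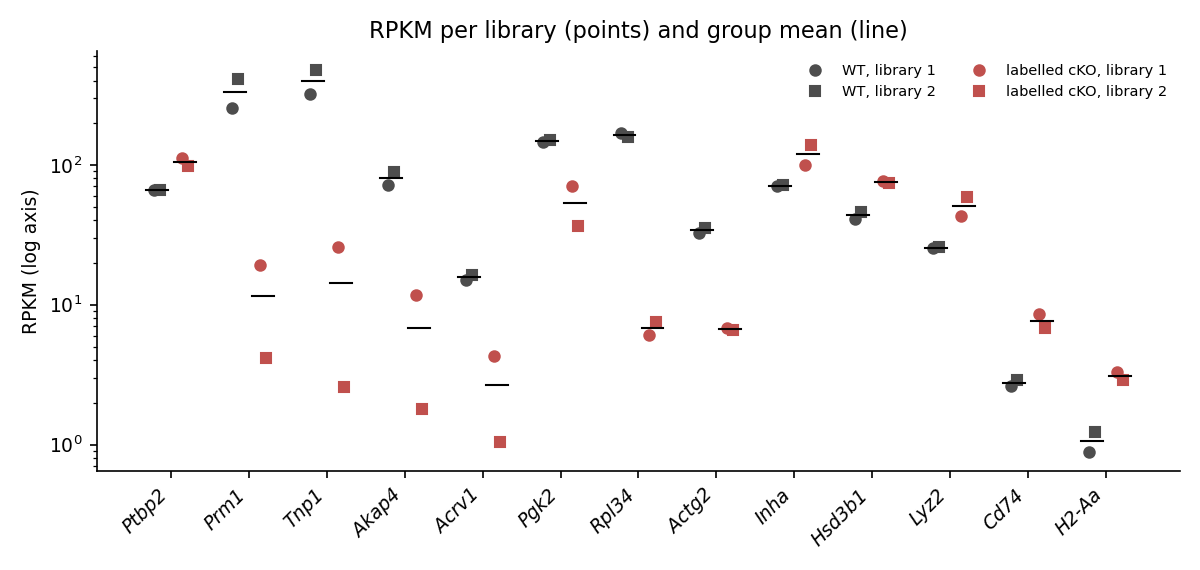
RPKM of 13 genes (log axis) in each library, with WT in grey and the libraries labelled cKO in red, circles for library 1, squares for library 2 and a line at the mean of 2 libraries. Spermatid genes such as Prm1 (332 against 11.6 RPKM) lie lower in both libraries labelled cKO and lowest in library 2, while Ptbp2, Inha, Hsd3b1, Lyz2, Cd74 and H2-Aa lie higher in both.

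Markers of other testis cells were few in the table. Of 13 macrophage genes, 3 are in the table and all 3 rose in limma: Lyz2, which encodes lysozyme, went from 25.6 ± 0.177 to 51.0 ± 11.7 RPKM (SD, n = 2), and Cd74 and H2-Aa, of antigen presentation, had log2 fold changes of 1.48 and 1.55 in the authors' deposited table. The Leydig cell gene Hsd3b1, of steroid synthesis, rose from 43.8 ± 3.68 to 75.2 ± 1.75 RPKM, with a BH-adjusted p of 0.0468 in limma. Inha, the Sertoli cell inhibin subunit, was at 70.9 ± 1.06 and 119 ± 27.3 RPKM, and its adjusted p in limma was 0.0727. Because RPKM is a share of a library's reads, the fall of spermatid transcripts could raise these and other genes listed as higher. How far it did was not tested for these markers. Actg2, a smooth muscle actin and the only 1 of 6 myoid list genes in the table, fell in limma. Its log2 fold change was -2.35 in the authors' deposited table, and 1 gene does not show a change of myoid cells. Of the spermatocyte list, Pgk2 fell by 1.46 and Ccna1 was listed at -0.86 on the log2 scale in the authors' deposited table, and Ccna1 did not pass in limma (BH-adjusted p = 0.0695). None of the 16 spermatogonia, 5 endothelial, 6 erythroid or 7 epididymis genes is in the table. Adjusted over the list alone, limma called 26 spermatid genes, 3 macrophage genes, and 1 gene each of the spermatocyte, Leydig and myoid lists, as it did over all genes tested.

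The largest rises were those of Mir298 (log2 fold change 2.11), Scgb2b1-ps (1.83), Mall (1.62), H2-Aa (1.55) and Cd74 (1.48) in the authors' deposited table, and all 5 rose in limma. Mir298 and H2-Aa were at 1.11 ± 0.502 and 1.06 ± 0.240 RPKM (SD, n = 2) in WT, near the low end of the table. Tmem38a (1.35), Nrk (1.30) and Trib2 (1.26) followed in the authors' deposited table but did not pass in limma. The histone genes Hist1h3f (1.30) and Hist1h2bf (1.25) passed in limma, but their close copies can share reads. By Fisher's exact test on direction, with BH adjustment over 6 lists, 3 of 3 macrophage genes were listed as higher against 60 of 985 other genes (p = 0.00149). Its units are genes and not mice, so this p does not measure a change of macrophages between genotypes. From labelled cKO library 1 to library 2, Lyz2 was higher (log2 ratio 0.47) but Cd74 (-0.35) and H2-Aa (-0.18) were lower. In the same exact test the spermatid list had 0 of 26 higher against 63 of 962 (p = 0.605). Most genes of the table are lower, so even 0 of 26 higher could not pass, and the test cannot decide. The exact p was 0.128 for the Sertoli and for the Leydig list, with 1 of 1 gene higher in each, and 1 for the spermatocyte and myoid lists. With 1 gene in a list the unadjusted exact p is at least 0.0638, so the Sertoli, Leydig and myoid lists could not pass. The limma calls of the 3 macrophage genes and of Hsd3b1 were lost without WT library 1, without WT library 2 and under the replicate block, in each of which 0 of them passed, and that of Pgk2 was lost without either WT library. With a pseudocount of 0.1, 2 of the 3 macrophage genes passed and Hsd3b1 did not, and among genes above the median expression 0 of 1 macrophage gene and 0 of 1 Leydig gene passed.

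The libraries labelled cKO differed from each other. RPKM was lower in library 2 than in library 1 for all 26 spermatid genes, with a median log2 ratio of -2.22, and for 877 of the 925 genes listed as lower. Against the WT mean, the median spermatid gene was at -2.47 on the log2 scale in library 1 and at -4.73 in library 2. Of the 63 genes listed as higher, 51 were higher in library 2 than in library 1. Rpl34, a ribosomal protein gene, stood at 168 and 158 RPKM in WT libraries 1 and 2 and at 6.12 and 7.50 RPKM in labelled cKO libraries 1 and 2, and so did not share this difference. The WT libraries lay closer together, with a median log2 ratio of 0.20 between library 2 and library 1 over the spermatid list and a higher value in library 2 for all 26 genes.

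**Figure D2:**
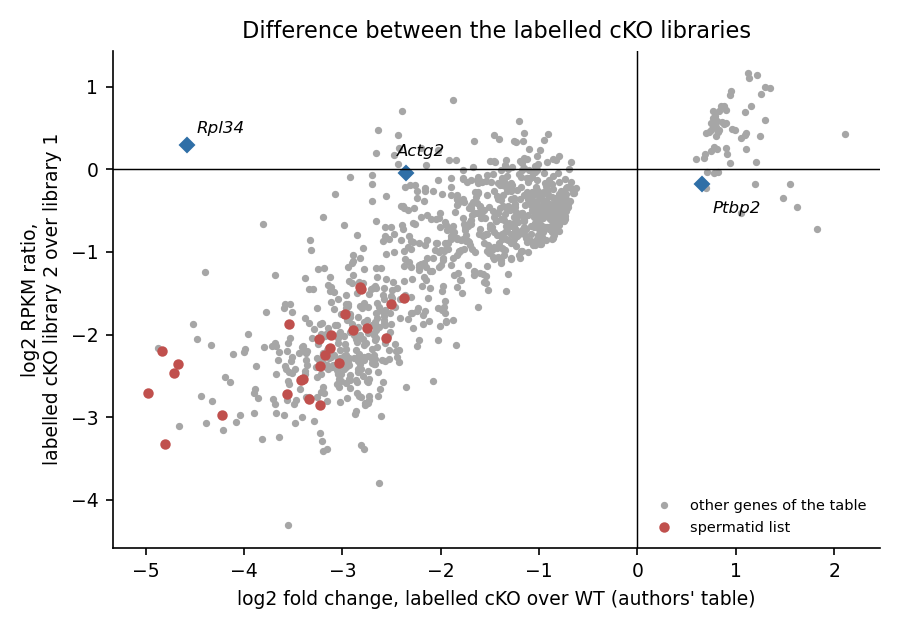
For each of the 988 genes, the log2 fold change of the labelled cKO over WT from the authors' deposited table (x axis) and the log2 RPKM ratio of labelled cKO library 2 over library 1 (y axis), with the 26 spermatid genes in red and Rpl34, Ptbp2 and Actg2 as blue diamonds. Spermatid genes have a median ratio of -2.22 on the y axis, while Rpl34, at -4.58 on the x axis, has a ratio of 0.29.

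The splicing table lists events in 915 genes, none with a p-value, and the sign of ΔPSI differed by type of event. Retained introns had a negative ΔPSI in 174 of 193 nonzero events, with 9.84% positive against 44.9% in the other types. Tandem cassette exons went the other way, with 66 of 110 positive (60% against 37.1%). Single cassette exons, the most frequent type with 741 events, were nearly balanced, with 341 positive and 385 negative (47.0% against 27.3%). Alternative 3' splice sites (26.8% positive against 40.2%) and 5' splice sites (24.5% against 39.9%) were more often negative, and mutually exclusive exons were positive in 8 of 31. Over all types 726 events were negative, 469 positive and 28 at 0. By Fisher's exact test of each type against the others, with BH adjustment over 6 types, p was 5.38e-22 for retained introns, 2.65e-11 for cassette exons, 9.95e-06 for tandem cassettes, 0.0282 and 0.0361 for 3' and 5' splice sites and 0.138 for mutually exclusive exons. The 193 retained introns, at 9.84% positive, are among the events that cassettes and each other type were compared with. The 6 tests are therefore not separate findings. With 1 event per gene the call of the 5' splice sites was lost (28.9% against 40.4%, exact p = 0.178 with BH adjustment). Among the 257 events of 20 points or more, none of the 6 types passed, with p from 0.679 to 1: retained introns were at 23.1% positive against 38.1%, 3' splice sites at 25.0% against 37.3%, cassettes at 39.4% against 31.5% and tandem cassettes at 38.7% against 36.3%. The 5' splice sites turned to 41.7% positive against 36.3%. Events of 1 gene are not independent, and the same libraries had 26 of 26 spermatid genes in the table lower, beside the macrophage, Leydig, myoid and spermatocyte genes given above. Whole testes were sequenced, so a ΔPSI can also differ where the mix of cells differs. Neither these values nor the splicing results below can tell a change of splicing within cells from a change in that mix.

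**Figure D3:**
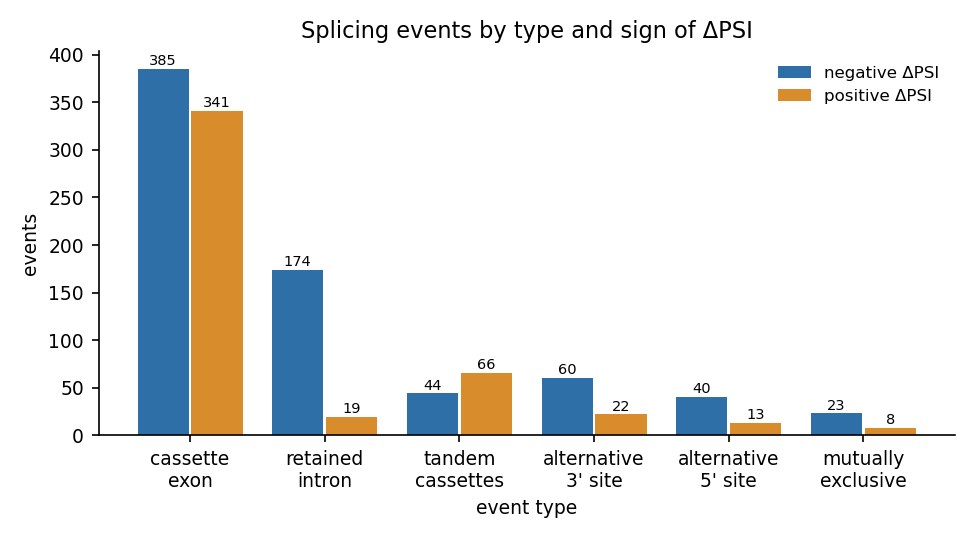
Number of splicing events (y axis) of each type (x axis) with a negative (blue) or positive (orange) ΔPSI, with events at 0 left out. Retained introns have 174 negative and 19 positive events, whereas tandem cassette exons have 44 negative and 66 positive.

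The largest negative ΔPSI was -83 for tandem cassettes of Ablim3, an actin-binding protein gene, on chromosome 18 (mm9 61976576 to 61978741). A 480-nt cassette exon of Wdr52 on chromosome 16 (44414711 to 44415190) had a ΔPSI of -76, and a 36-nt exon of Ehbp1l1 on chromosome 19 (5720972 to 5721007), of the length of a coding exon, had -71. A 99-nt exon of Fmnl1, a formin gene that acts on actin, on chromosome 11 (103059449 to 103059547) had -64. A 74-nt exon of Pum2, which encodes a Pumilio RNA-binding protein, on chromosome 12 (8706955 to 8707028) and an alternative 3' splice site of Fam116b on chromosome 15 (89017386 to 89017480) each had -61. The exons of Wdr52, Fmnl1 and Pum2 have the length of annotated exons that are not wholly coding. Rapgef1 (-60), Atl3 (-59), Lrrfip2 (-57) and Mllt10 (-57) followed. The largest positive ΔPSI was 68 for tandem cassettes of Immt, a mitochondrial inner membrane gene, on chromosome 6 (71802724 to 71803262). An alternative 3' splice site of Zfp62 on chromosome 11 (49027725 to 49028156) had 60. A 185-nt exon of Ccdc108 on chromosome 1 (74978418 to 74978602), of the length of a coding exon, had 57. So did a 209-nt exon of Rangap1 on chromosome 15 (81556504 to 81556712), not wholly coding. Rangap1 encodes the GTPase-activating protein of the nuclear transport GTPase Ran. An alternative 5' splice site of Bbx on chromosome 16 (50330947 to 50331215) had 53. Idh3b (51.5), Scamp2 (49), Lrp5 (48), Ccdc91 (48) and Arfgef2 (46) followed. These values are the authors' and carry no replicate error, so their order is not tested.

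Genes of membrane traffic were frequent in the splicing table. Of the 61 genes in that list, 22 had an event, 15 of them of 20 points or more, and the largest event was negative in 16 and positive in 6. They include Dctn1, a subunit of the dynein partner dynactin (a 21-nt exon at -53), the clathrin adaptor genes Ap1b1 (a 21-nt exon at -50), Ap2a1 (-50) and Ap2b1 (-43), the sorting nexin gene Snx14 (-49) and the synaptojanin gene Synj1 (23). Of 95 actin cytoskeleton genes, 15 had an event, 10 of them of 20 points or more, among them Fmnl1 (-64), the myosin gene Myo18a (-36), Enah (-34.5) and Mprip (40). Of 65 RNA-binding genes, 14 had an event, but only Elavl2 (-27) reached 20 points. Of 61 adhesion and junction genes, 7 had an event, with Scrib at -50, Mllt4 at -45 and Magi3 at -28. Of 40 known PTB targets, 5 had an event: Unc13b (-20), Ptbp2 (-9), Clta (-2 and -1), Tpm1 (13) and Pkm (13 and 11).

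Against the 900 genes that are only in the expression table, Fisher's exact test with BH adjustment over 5 lists gave a higher share among the 915 spliced genes for membrane traffic (2.40% against 0.222%, p = 0.000163), RNA binding (1.53% against 0.111%, p = 0.00235) and the actin cytoskeleton (1.64% against 0.222%, p = 0.00377). The p was 0.0777 for known PTB targets (0.546% against 0%) and 0.343 for adhesion and junctions (0.765% against 0.333%). The comparison genes were themselves selected and are rich in spermatid genes, so the test sets the 2 tables against each other and not against all genes expressed in testis. Among events of 20 points or more the RNA-binding share was 0.461% and no longer passed, and with names matched through synonyms a further PTB target (0.656%) brought that list past the threshold. From these lists the expression table held Fmnl1 (log2 fold change -1.24), Limch1 (-1.01) and Tln2 (-1.34) of the actin list and Amotl1 (-1.11) and Ank2 (-1.10) of the adhesion list, all of which fell in limma, and Klc1 (0.90) of membrane traffic, which rose. Adjusted over the list alone, limma called 3 actin, 2 adhesion and 0 membrane traffic genes, so the call of Klc1 was lost, as it was with a pseudocount of 0.1. Without WT library 1, without WT library 2 and under the replicate block, 0 of these 6 genes passed. Pvrl3 (-0.71), Magi3 (0.71), Sh3kbp1 (-1.02), U2af2 (0.69) and Ptbp2 (0.66) did not pass in limma, and all these fold changes are from the authors' deposited table. Of the cell type lists, 5 spermatocyte genes had an event, from -14 in Mybl1 to 9 in Hormad1, and 3 spermatid genes, Izumo1 (-26), Gsg1 (24) and Crem (9 and -2), while the other 8 cell type lists had none.

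**Figure D4:**
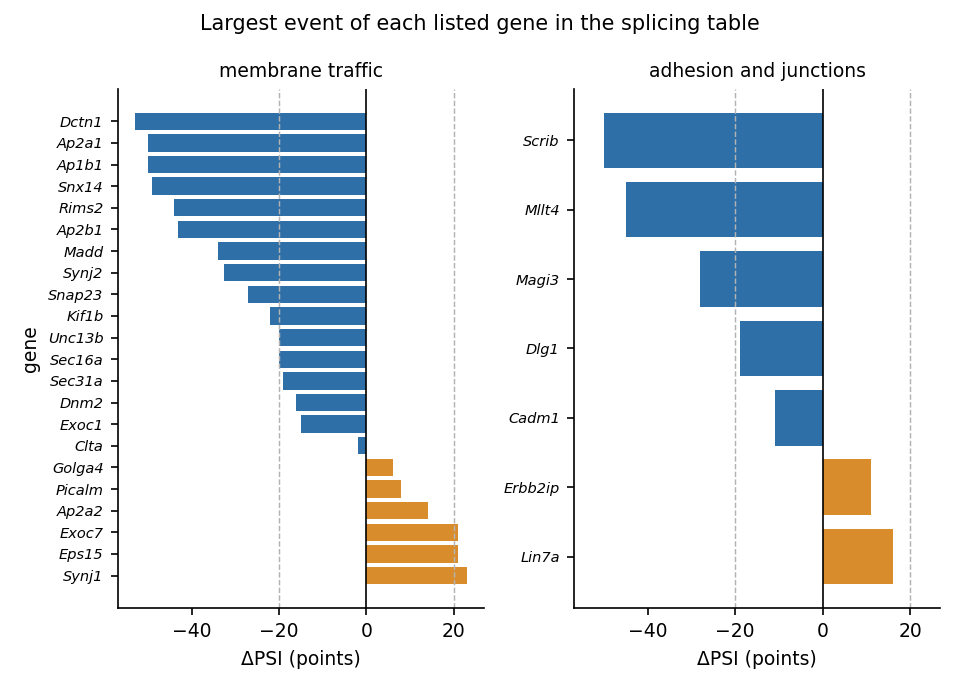
ΔPSI in percentage points (x axis) of the largest event of each gene of the membrane traffic and the adhesion and junction lists that is in the splicing table, with dashed lines at 20 points either way. In membrane traffic 16 of 22 genes are negative, down to -53 in Dctn1.

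Cassette exons with negative ΔPSI were shorter than those with positive ΔPSI. Their median length was 90 nt over 385 exons, against 111 nt over 341 exons, a difference of -21 nt (permutation p = 4e-05). The exons kept the reading frame, by a length divisible by 3, in 58.2% of negative and 53.4% of positive events, with no difference detected by Fisher's exact test (p = 0.203). The median absolute ΔPSI was 12 and 11 points with no difference detected (permutation p = 0.604). Among cassettes of 20 points or more the median lengths were 90.5 and 106 nt and the permutation p was 0.113.

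The second deposited splicing table, with 257 events, held all events of 20 points or more. Of these 163 were negative and 94 positive, and 29 reached 50 points, 22 of them negative. The share of positive events was 36.6%, against 40.0% of the 938 other nonzero events (Fisher's exact p = 0.349), and the share of cassette exons was 64.2% against 59.6% (p = 0.196). Retained introns made up 10.1% of it, against 17.7% of the other events (Fisher's exact p = 0.00297). Over the whole table the median absolute ΔPSI was 11 points, and 260 events were below 5 points.

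Spliced genes and genes that differed in expression shared 88 genes, 9.62% of the spliced genes. Wdr52 had a ΔPSI of -76 and fell from 28.6 ± 0.255 to 10.3 ± 2.54 RPKM (SD, n = 2). Fmnl1 (-64) and Grip1, a scaffold protein gene (-50), also fell, as did Ccdc91 (48), Cacnb1 (-47), Dgkh (-45), the fatty acid ligase gene Acsl1 (42), Rpl34 (-40) and Akap1 (37), each in limma. Scamp2 (49) was at 40.1 ± 0.304 and 24.8 ± 0.00707 RPKM, and its BH-adjusted p in limma was 0.0599. The Rpl34 event is a retained intron on chromosome 3 (mm9 130431969 to 130432220), 11 megabases from the Ptbp2 event. If 10000, 15000 or 20000 genes could have entered both tables, 90.4, 60.3 or 45.2 shared genes would be expected of independent lists, and the true number is unknown. Of the 88 genes, 84 were listed as lower and 4 as higher. These 4 were Magi3, Ptbp2 and, outside the naming rule and chosen after their values were seen, Rnps1 and Srrt. The share listed as higher was 4.55%, against 6.56% of the other 900 genes (Fisher's exact p = 0.647). Among genes with an event of 20 points or more, 31 were shared.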

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

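Of 31 results, 94 values under other settings were computed, of which 61 kept their direction and side of the threshold, or for counts stayed within 1.5 times. The 61 include every value at an adjusted p under 0.01. Those could not differ, since the largest deposited adjusted p is 0.0099, so they show no robustness. The crossed pairing and the folds of single libraries labelled cKO were chosen after seeing the data. In limma, against 829 lower and 19 higher genes, the replicate block gave 622 and 2 and the crossed pairing 758 and 10, with 2 of 3 macrophage genes and 0 of 1 Leydig gene; same-numbered libraries deviated in opposite directions, with a correlation across genes of -0.33, and the labels do not say that the numbers pair mice. Leaving out 1 library gave 353 to 925 lower and 0 to 63 higher genes: with a labelled cKO library out, the lone library is assumed to vary like the closely spaced WT libraries, and with a WT library out like the more widely spaced libraries labelled cKO. Genes above the median expression gave 312 and 1, absolute log2 fold changes of at least 1.5 gave 2 higher, and leaving out predicted models 30 higher. In the authors' deposited table, against 925 lower and 63 higher, log2 fold changes of at least 1.5 left 594 and 4, genes above the median expression 463 and 31, and an adjusted p under 0.001 left 6 higher; an adjusted p under 0.01 removed no gene. The cause was not tested, except that fewer genes enter under each filter. The median log2 fold of the spermatid list, -3.23, was -2.47 in labelled cKO library 1 alone and -4.73 in library 2 alone. Events of at least 20 points numbered 163 negative and 94 positive, and of at least 30 points 79 and 43. At 20 points the call on the positive share was lost for cassettes (39.4%), tandem cassettes (38.7%), 3' splice sites (25.0%) and retained introns (23.1%), the last 2 still below the other types (37.3% and 38.1%), and the share turned for 5' splice sites (41.7%), with 12 to 165 events per type; with 1 event per gene it was lost for 5' splice sites (28.9%). Also at 20 points, the exon length difference of -15.5 nt and the RNA-binding share of 0.461% lost their calls, with fewer events in each test. Both tables then shared 31 genes, 14.3% of the spliced genes against 9.62% at first. Synonyms brought known PTB targets (0.656%) past the threshold through 1 further gene. The subset had no other events to compare with at 20 points. Count models, low-count filters, splicing p-value or coverage filters, and fits of splicing without a library or with a block were not run, for want of such values. Depth, unknown here, limits genes near 1 RPKM and every ΔPSI.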

Other observations

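The tests in this part were chosen after the values were seen, except the test of the share of genes far from a mixture with WT RNA. Symbols were grouped by their letters before the first digit, and the 28 groups with at least 4 genes in the expression table were tested for direction by Fisher's exact test with BH adjustment. Collagen genes were mostly listed as higher in the libraries labelled cKO, 5 of 6 against 58 of 982 other genes (exact p = 0.000145), from 0.77 for Col3a1 to 1.22 for Col6a3 on the log2 scale of the authors' deposited table, while Col22a1 was at -2.57. None of the 5 passed in limma (BH-adjusted p of 0.0898 or more), and each was higher in labelled cKO library 2 than in library 1, as with Col1a2 at 16.4 and 30.7 RPKM against 12.8 and 11.8 in WT. Histone genes named Hist were listed as higher in 4 of 4 against 59 of 984 (exact p = 0.000211), and Hist1h2bf and Hist1h3f of them rose in limma. These messages mostly lack a poly(A) tail, and the protocols name both poly(A) selection and ribosomal RNA depletion. The spermatid genes lay lower than the other 899 genes listed as lower, with medians of -3.23 and -1.94 (permutation p = 1e-05, the smallest 100000 resamples can give).

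Very short cassette exons were mostly negative. Of cassettes of 27 nt or less, 35 were negative and 5 positive, or 9.09% of 385 negative and 1.47% of 341 positive cassettes (Fisher's exact p = 4.57e-06). With 15 nt as the limit the counts were 9 and 2 (exact p = 0.0688), and with 50 nt they were 74 and 27 (exact p = 9.07e-06). Among cassettes of 20 points or more, 8 of 100 negative and 1 of 65 positive exons were of 27 nt or less, a difference that was not tested. The 35 negative exons include some at a ΔPSI of -1. Members of the membrane traffic list among them are the 21-nt exons of Dctn1 (-53) and Ap1b1 (-50), the 27-nt exon of Snx14 (-49), the 12-nt exon of Dnm2 (-16) and the 21-nt exon of Exoc1 (-15). Most of the 35 lie in genes outside that list, and an excess of traffic genes among very short exons was not tested. Fhod1 (24 nt, -49) and Plec (15 nt, -44), named after their values were seen, encode cytoskeletal proteins.

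The libraries labelled cKO differ from each other in 877 of the 925 genes listed as lower, which lie below library 1 in library 2, while 51 of the 63 genes listed as higher lie above it. A single scale factor between the libraries would move both groups alike, and their medians differ by 1.37 on the log2 scale (permutation p = 1e-05, the smallest possible), which argues against it. If WT RNA mixed into library 1 were the whole difference, the median of the spermatid list would need 14.4% WT RNA. Prm1, Prm2, Tnp1, Tnp2 and Spem1, 5 of its 26 genes (19.2%), lie more than 1.5 times below the least that this share of the lower WT library would leave. Prm1, for example, is at 19.1 against 36.5 RPKM. These 5 are the largest falls of the list and the check was chosen after the values were seen, so it does not decide the question. A share up to 6.79% would leave no gene of the list below that value. In the test set before, 81 of 555 genes at least 4-fold lower in library 2 (14.6%) lay more than 1.5 times from the 14.4% mixture, between the bounds of 5% and 20%. Under the mixture, the median log2 ratio of library 2 over library 1 for the genes listed as higher would be 0.116, against 0.453 as measured. For the genes listed as higher, this argues against WT RNA in library 1 as the whole difference. WT RNA as a part of it cannot be told apart from a difference between the mice. Fewer or less mature spermatids in the mouse of library 2 may also contribute. The spermatid list lies below all other genes listed as lower (difference of medians -1.34, permutation p = 5e-05). The list is not detectably below the 354 others that fell at least as far as its least lowered gene (difference -0.0844, permutation p = 0.573). Those 354 were matched on folds from the same libraries and can include spermatid genes outside the list, which fewer spermatids would lower alike. The test therefore cannot decide, and this explanation stays open.

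Rpl34 fell as far as spermatid genes but equally in both libraries labelled cKO, with a log2 ratio of library 2 over library 1 of 0.29. Loss of spermatids would give a lower value in library 2, as in all of the other 176 genes down 8-fold or more (100%), which argues against it for Rpl34. A candidate explanation is sequence on chromosome 3 that came with the targeted Ptbp2 locus. Of 57 genes that go against the difference between the libraries, 9 lie on chromosome 3, against 54 of 918 others (odds ratio 3, Fisher's exact p = 0.0083). Over 21 chromosomes the BH-adjusted p is 0.174 and the question stays open. The 9 include Hsd3b1, the only Leydig list gene given above, and Magi3, both listed as higher, so the same open question covers them. Reads shared with processed copies could also matter, since the annotation holds 2 Rpl34 pseudogenes, and without read alignments this cannot be told apart from the other explanations.

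Ptbp2 is listed as higher in the libraries labelled cKO. Exchanged labels of single libraries would put 1 mouse of each genotype under each label and split each pair, but Ptbp2 is at 65.7 and 66.6 against 111 and 98.2 RPKM. All 988 genes of the table separate the labels by selection, but selection does not set how much of a list enters: in 26 of all 33 spermatid genes (78.8%), those absent counted against, both libraries labelled cKO lie below both WT libraries, which argues against it. An exchange of both pairs would leave these values as they are; it would need WT testes to be those with 26 of 26 spermatid genes in the table lower, by a median of 9.38-fold, and stays open because no genotype was checked. Dilution by missing spermatids may raise it, yet Ptbp2 is lower in library 2 (log2 ratio -0.18), where spermatid genes are lowest, and 12.9% of the other 62 genes listed as higher have a lower ratio, so this stays open. Its own 34-nt exon, at a ΔPSI of -9, could alter the stability of the transcript, and because the order of subtraction is not stated this cannot be told apart from more or from less inclusion.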
